A study of Mus musculus with 6 samples.

How the data were processed

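Single-cell RNA sequencing (10x Genomics droplets) was performed on mouse aortic tissue from 6 samples, 3 from floxed controls and 3 from mice with Best3 deleted in smooth muscle. The authors deposited 1 matrix of whole-number UMI counts for 55450 genes and 60871 barcodes, and the file headers name cellranger-6.1.2 as the software that wrote it. Cell Ranger 3.1.0, Seurat 3.1.1, bcl2fastq 5.01 and the build GRCm38 are named per the submitters' processing notes, so the Cell Ranger versions of the 2 sources differ. Whether read depth was equalised between libraries when they were combined is not given in the sources used here. All 55450 gene identifiers were found in the GENCODE M21 annotation of GRCm38, from which coordinates were taken. The deposited values are whole numbers and so were not scaled or log-transformed, but subsampling to an equal depth would also leave whole numbers. Each gene's symbol is the one paired with its identifier by the authors.

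The barcodes carry 6 suffixes, which tell 6 libraries apart but match no sample label. No map from cells to samples was therefore available, and no cell was assigned to a genotype. The planned comparisons of knockout against control (edgeR on counts summed per sample, permutation tests of shares, gene list tests) were not made, and no p-value is given anywhere. Libraries 1 to 6 are named after their suffix, and their values are given singly or as a range and median. Intervals are exact 95% Poisson or Clopper-Pearson intervals and, like limits of 3 counts for values of 0, cover counting error only.

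Barcodes with at least 500 detected genes and at most 20% mitochondrial counts were kept, and doublets called by Scrublet in each library (scanpy 1.11.5) were removed. Scrublet called between 3.91% and 11.5% of barcodes per library, and 50652 cells were kept. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen within libraries. Mitochondrial, ribosomal protein and all functional list genes were left out of the variable genes. Cells were clustered on 30 principal components and 20 nearest neighbours by Leiden clustering (leidenalg 0.10.2, resolution 0.5), which gave 30 clusters. No batch integration was applied. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 were used.

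Each cluster was compared with 25 marker lists fixed before the data were examined. It took the name of the list with the highest mean log2 ratio to the median cluster, with 5 CPM added to both. A cluster stayed unnamed if fewer than 3 markers reached 10 CPM and 2 times that median, or if its 10 leading genes held more markers of another list. It also stayed unnamed if its median depth, times 3, was below its libraries' median with no own marker among its leading genes, or if a second list scored within 0.3 log2 units. The 0.3 margin was set after clusters had been seen and affected only a cluster of 45 cells. The names come from these rules, not from an annotation by the authors.

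Counts were summed per class and library and expressed as CPM (UMIs of a gene per 1e6 UMIs). A total of 21 functional lists with 287 genes, of which 286 are in the matrix, had also been fixed. A list gene was placed in a class if its CPM there was at least 4 times that in every other class of at least 200 cells, and highest in every library holding at least 20 cells of the class. Between clusters of the smooth muscle-like class the factor was 2, among genes reaching 50 CPM on either side and in the same direction in every library with at least 20 cells. Spread between libraries was the ratio of the highest to the lowest library CPM, for genes with at least 50 counts in each. These are rules of size and not tests. Named genes are Best3, up to 4 placed and 2 unplaced genes of highest CPM per list, the 4 list genes of at least 50 CPM with the largest ratio per smooth muscle-like cluster, and the 6 widest and 2 narrowest library ratios. Other genes named in the text were chosen after their values were seen. Cells with Xist alone and cells with Y-linked UMIs alone were compared within libraries 1, 3 and 4 after the sex-linked genes had been seen. A gene differed if it reached 30 CPM on either side and the ratio, with 2 CPM added to both, was at least 1.5 in the same direction in all 3 libraries, limits that were set after a first look at the values. As a reference, 20 random splits of the Y-linked cells alone, and so of fewer cells, were compared in the same way. Markers and sex-linked genes serve as checks.

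The size rules were tested on simulated counts for 2000 genes, 200 of them raised by known factors. Placement recovered 92.0% of genes raised 6-fold, 100% of those raised 8-fold and 0% of those raised 3-fold, with 0 of 1800 flat genes placed. The simulated counts held no RNA carried over between classes. Their genes were also more abundant than some placed ones, such as Ibsp at 8.40 CPM, so recovery in the data may be lower. In the simulation of cluster 10 the rule called 100% of genes raised 3-fold and 0% of those raised 1.5-fold. With counting error alone, the library ratio of unchanged genes had a median of 1.04 and 0% reached 2, for genes more abundant than many on the lists. A smooth muscle-like cluster of another setting counted as the counterpart of the cluster with which it shared most cells over their union, and of no other. Alternatives covered the gene and mitochondrial limits, doublets, clustering resolution, variable genes, the size factors, library weights, scaling, depth and each library left out. Cells were not clustered or named again when a library was left out. Genes with a symbol shared by several identifiers were read from the first one.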

Results

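The data describe single cells of the mouse aorta, taken from 3 samples with a floxed Best3 gene and 3 samples in which Best3 was deleted in smooth muscle. Best3 encodes bestrophin 3, a member of a family of chloride channel proteins. The series asks about the function of vascular smooth muscle cells in aortic disease. The 6 libraries in the combined matrix held between 7475 and 16269 barcodes and between 51813179 and 96144873 UMIs. The median depth per barcode lay between 4708 UMIs in library 5 and 6289.5 UMIs in library 2. Because no library could be tied to a genotype, no value below compares knockout with control, and the cell classes, their gene programs and the differences between libraries are described.

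The deleted gene itself was detected at the edge of sensitivity. Best3 (ENSMUSG00000020169) lies on the plus strand of chromosome 10 at positions 116986314 to 117025040 of GRCm38 and is annotated as protein-coding. Only 26 Best3 UMIs, in 26 barcodes, were present among 399340994 UMIs. Smooth muscle-like cells held 20 of them, a level of 0.142 CPM (95% interval 0.0869 to 0.220) and 0.151% of cells (0.0921 to 0.233) at a median depth of 10689.5 UMIs. Fibroblast-like cells, taken as the background, held 5 UMIs, or 0.0443 CPM (0.0144 to 0.103) and 0.0300% of cells (0.00973 to 0.0699), at a median of 6450 UMIs. The CPM intervals of these 2 classes overlap. All kept cells outside the smooth muscle-like class together held the same 5 UMIs, or 0.0228 CPM (0.00740 to 0.0532), an interval below that of smooth muscle-like cells. Without library 1, smooth muscle-like cells stood at 0.0777 CPM (0.0355 to 0.147) and the other kept cells at 0.0166 CPM (0.00343 to 0.0486), and these intervals overlap. Whether such intervals overlap is not a test of a difference. No UMI was found in 8368 endothelial cell-like cells at a median depth of 4324.5 UMIs, which allows up to 0.0359% of cells with a UMI, or in 3216 macrophage-like cells at 5052.5 UMIs, which allows up to 0.0933%. At this depth such limits do not bear on whether these cells express the gene.

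Among smooth muscle-like cells, library 1 held 11 Best3 UMIs, or 0.446 CPM (0.223 to 0.799). The other libraries held 1 to 3 UMIs each, between 0.0369 and 0.123 CPM. These counts are too few to check any label, and the exons removed by the deletion are not given in the sources used here, so a UMI could also come from a transcript of the recombined gene.

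The kept cells included 13 named classes, led by fibroblast-like, smooth muscle-like and endothelial cell-like cells. Not all of these classes need come from the aorta itself. Fibroblast-like cells (Pdgfra, Dcn, Lum) made up 33.0% of the 50652 kept cells (95% interval 32.5 to 33.4), with libraries between 26.2% and 36.6%. Smooth muscle-like cells (Myh11, Acta2, Cnn1) made up 26.2% (25.8 to 26.6), from 13.8% in library 4 to 38.7% in library 6. Endothelial cell-like cells made up 16.5% (16.2 to 16.8), from 9.09% in library 5 to 24.8% in library 4. Macrophage-like cells made up 6.35% (6.14 to 6.57), with libraries between 5.33% and 8.50%. These libraries differed by far more than counting error, and dissociation and dissection can set such shares.

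**Figure D1:**
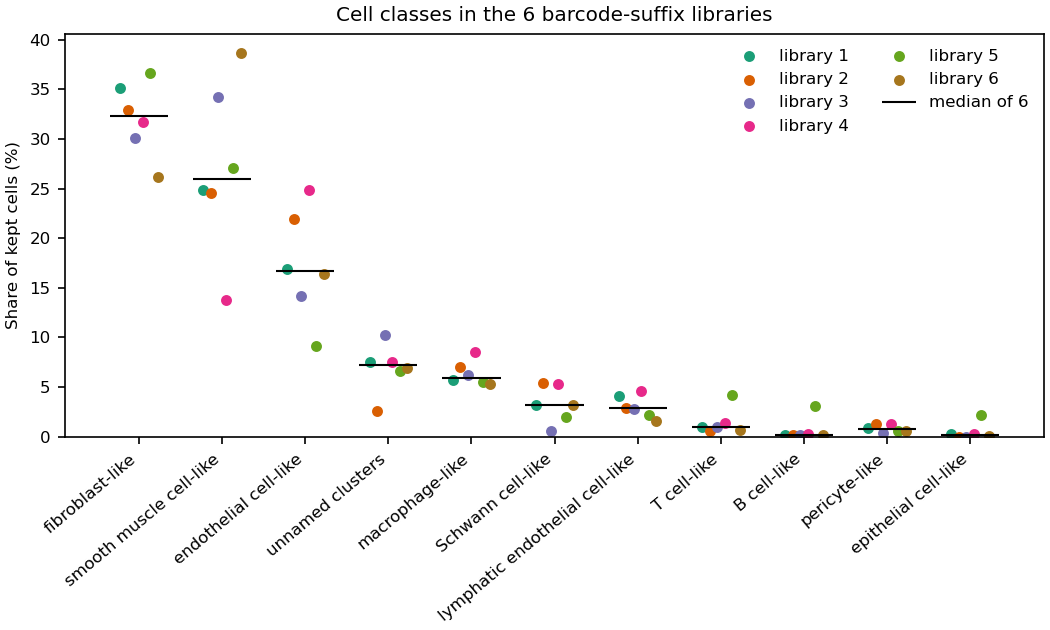
Share of kept cells (%) in each class of at least 200 cells, one point per barcode-suffix library and a line at the median of the 6. Smooth muscle-like cells range from 13.8% to 38.7%, and T cell-like, B cell-like and epithelial cell-like cells stand highest in library 5 at 4.17%, 3.11% and 2.14%.

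Smaller classes were Schwann cell-like (1657 cells, from 0.552% in library 3 to 5.37% in library 2), lymphatic endothelial cell-like (1548 cells), T cell-like (940), B cell-like (504), pericyte-like (425) and epithelial cell-like (348). Adipocyte-like, neutrophil-like and mesothelial cell-like clusters held 120, 63 and 49 cells. The leading genes of the adipocyte-like cluster also included the steroid synthesis genes Hsd3b1, Cyp21a1 and Cyp11a1, so its name may not cover all its cells. Library 5 supplied 578 of the T cell-like, 431 of the B cell-like and 297 of the epithelial cell-like cells. A further 5 clusters with 3456 cells (6.82%, libraries 2.57% to 10.2%) stayed unnamed. Among them were 2066 cells of low depth and 959 cells led by Lyz1, Ear2, Chil3 and Ccr2, which carried markers of both monocytes and dendritic cells. Pericyte-like cells were not found as a class of their own under 4 alternative settings.

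Of 286 functional list genes, 50 were placed in 1 class. Macrophage-like cells took 22, fibroblast-like cells 9, smooth muscle-like cells 7, endothelial cell-like cells 5, pericyte-like cells 4, T cell-like cells 2 and lymphatic endothelial cell-like cells 1. Over the alternative settings the counts ranged from 16 to 94 in any class, 11 to 27 in macrophage-like, 0 to 20 in fibroblast-like, 0 to 16 in smooth muscle-like and 2 to 10 in endothelial cell-like cells. These genes were not used for clustering. Smooth muscle markers summed to 54879 CPM in smooth muscle-like cells. In the other classes of at least 200 cells except pericyte-like cells, they summed to between 2012 CPM (fibroblast-like) and 6326 CPM (T cell-like). Macrophage markers summed to 19051 CPM in macrophage-like cells and 59.1 CPM in smooth muscle-like cells. Smooth muscle genes may therefore reach lower ratios, and the counts of placed genes are not directly comparable between classes.

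The 7 genes placed in smooth muscle-like cells came from 3 lists, with 4 of 25, 2 of 16 and 1 of 17 members. In the list of contractile regulators and ion handling, 5 of 25 genes were placed. Itga8, an integrin subunit, reached 1523 CPM in smooth muscle-like cells against 204 CPM in pericyte-like cells, and its ligand Npnt reached 839 against 134 CPM. Kcnmb1, the smooth muscle subunit of the BK potassium channel, stood at 199 against 34.9 CPM. Notch3 was placed in pericyte-like cells at 785 CPM against 83.5 CPM in smooth muscle-like cells. Pericyte-like cells also carried smooth muscle markers, at a summed 38936 CPM against 1346 CPM for pericyte markers. Their mean log2 marker ratio was 3.58 for pericytes and 3.20 for smooth muscle, so placement there need not set pericytes apart from smooth muscle. Tpm2 and Cald1, which encode thin filament proteins, reached 5274 and 4557 CPM in smooth muscle-like cells and were not placed, since pericyte-like cells held 4500 and 3220 CPM. Ptgis, the prostacyclin synthase, stood at 1273 CPM against 292 CPM in fibroblast-like cells, and the ATP-gated channel P2rx1 at 79.2 against 19.7 CPM in pericyte-like cells. The endothelin receptor Ednra and the angiotensin receptor Agtr1a were placed in pericyte-like cells at 134 and 46.5 CPM, making 4 of 16 vasoactive genes placed. Ednra also stood at 66.7 CPM in smooth muscle-like cluster 10, where Notch3 was high too. Gucy1a1 (773 CPM in pericyte-like cells) and Ednrb (461 CPM in lymphatic endothelial cell-like cells) were not placed. In the modulated smooth muscle list, 1 of 17 genes was placed, Ibsp at 8.40 CPM, while Mgp and Ly6a were highest in fibroblast-like cells at 8034 and 1635 CPM (each in 5 of 6 libraries).

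Of 15 collagens, 3 were placed, all in fibroblast-like cells. Col1a2 stood there at 5539 CPM against 922 CPM in smooth muscle-like cells, Col1a1 at 2465 against 416 CPM, and Col14a1 at 956 against 239 CPM in Schwann cell-like cells. Col3a1 (2189 CPM in fibroblast-like cells) and Col18a1 (967 CPM in smooth muscle-like cells) were not placed. In the elastic fibre list, 1 of 13 genes was placed, Fbln1 in fibroblast-like cells at 1131 CPM. Eln, which encodes elastin, was highest in smooth muscle-like cells in 6 of 6 libraries at 1607 CPM, but endothelial cell-like cells held 697 CPM. Mfap5 was highest in fibroblast-like cells at 1073 CPM. None of the 18 genes on the list of heritable aortic aneurysm and dissection was placed. The most abundant on this list, Bgn, stood at 2968 CPM in fibroblast-like and 2896 CPM in smooth muscle-like cells. The list leaves out Acta2, Myh11 and Mylk, which served as smooth muscle markers, so it does not cover them. In smooth muscle-like cells of single libraries, Acta2 lay between 18209 and 24767 CPM and Myh11 between 5642 and 8115 CPM.

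Of 21 proteases, 3 were placed in fibroblast-like and 5 in macrophage-like cells. Mmp3 and Mmp2 stood at 935 and 474 CPM in fibroblast-like cells, and Ctsb and Mmp9 at 3200 and 281 CPM in macrophage-like cells. Ctsl (1621 CPM in fibroblast-like cells) and Ctss (1002 CPM in macrophage-like cells) were not placed. Of 9 inhibitors, Serping1 (3010 CPM) and Timp1 (211 CPM) were placed in fibroblast-like cells, Timp4 in endothelial cell-like cells (552 CPM) and A2m in lymphatic endothelial cell-like cells (12.4 CPM). Timp3 stood at 3364 CPM in pericyte-like and 3134 CPM in lymphatic endothelial cell-like cells, with pericyte-like cells highest in 1 of 6 libraries, and Timp2 was highest in fibroblast-like cells at 2963 CPM.

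Of 20 cytokines and chemokines, 11 were placed in macrophage-like cells, including Cxcl2 at 3999 CPM, Ccl7 at 1749 CPM and Ccl6 at 1564 CPM, and Ccl5 was placed in T cell-like cells at 2226 CPM. Cxcl12 and Cxcl1 were highest in pericyte-like cells at 921 and 460 CPM (in 5 and 4 of 6 libraries) and were not placed. Of 8 resident macrophage genes, 5 were placed in macrophage-like cells, among them Pf4 (3169 CPM), F13a1 (2200 CPM), Cd163 (1326 CPM) and Folr2 (774 CPM). Cbr2 (3768 CPM in epithelial cell-like cells, from 42.2 to 4155 CPM in 3 libraries and highest there in 1) and Lyve1 (1589 CPM in lymphatic endothelial cell-like cells, highest there in 4 of 6 libraries) were not. Of 7 lipid associated macrophage genes, 1 was placed, Trem2 at 150 CPM, while Apoe reached 12878 CPM in macrophage-like and 10104 CPM in Schwann cell-like cells, and Cd9 was highest in Schwann cell-like cells at 2828 CPM. The unnamed cluster of 959 cells with markers of both monocytes and dendritic cells, 524 of them in library 5, lies outside these classes. It exceeded macrophage-like cells for 4 of their 22 placed genes, including Il1b, at 987 against 281 CPM.

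Endothelial cell-like cells took 4 of 10 genes of endothelial flow and activation. The fatty acid binding protein Fabp4 reached 13909 CPM, P-selectin Selp 319 CPM, connexin 40 (Gja5) 150 CPM and the chemokine receptor Ackr1 54.9 CPM. Cd36 (1809 CPM, in 6 of 6 libraries) and Klf2 (1634 CPM, in 4 of 6) were highest there without being placed.

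**Figure D2:**
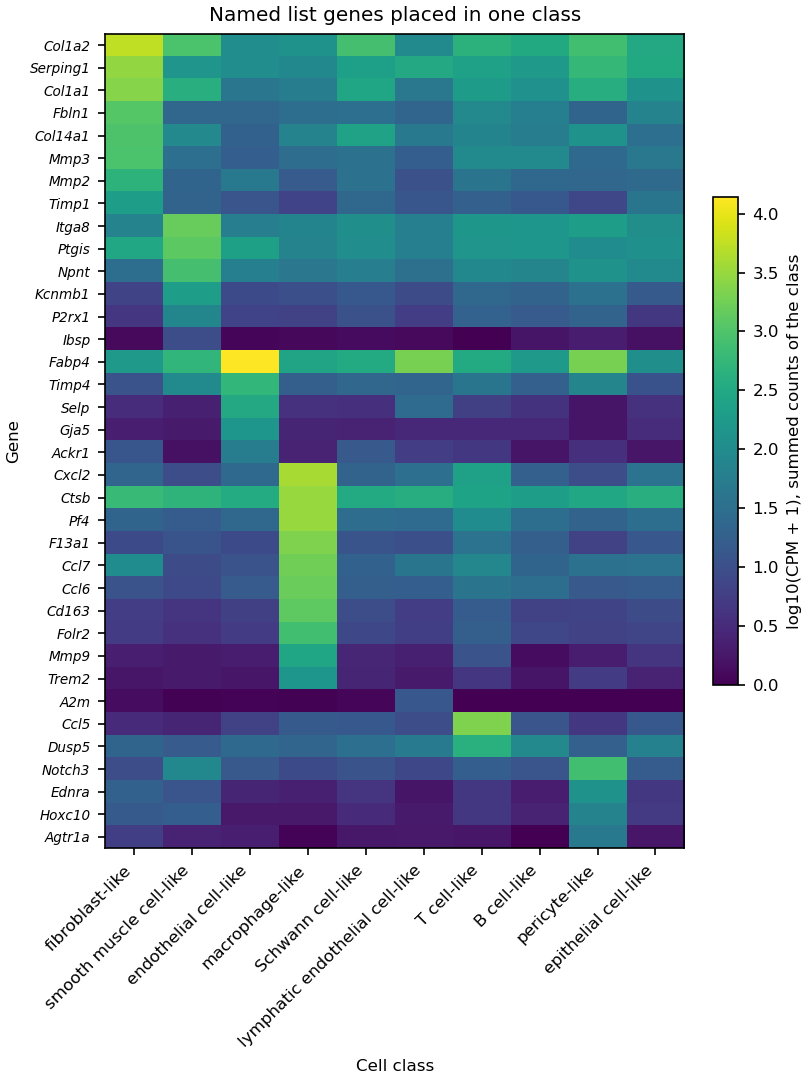
CPM of the named genes that were placed in 1 class (rows), on a log10(CPM + 1) colour scale, in summed counts of each class of at least 200 cells (columns). Col1a2 is brightest in fibroblast-like cells (5539 CPM), Itga8 in smooth muscle-like cells (1523 CPM), Fabp4 in endothelial cell-like cells (13909 CPM) and Cxcl2 in macrophage-like cells (3999 CPM).

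Signalling lists were spread over the classes. None of the 18 genes of the MEKK2/3 and MAP kinase cascade was placed. Map3k2, which encodes MEKK2, lay between 34.4 CPM in B cell-like and 85.6 CPM in macrophage-like cells and stood at 61.3 CPM in smooth muscle-like cells. Map3k3, which encodes MEKK3, lay between 23.3 and 76.0 CPM and stood at 40.5 CPM in smooth muscle-like cells. The most abundant of the list were Mapk3 (ERK1) at 232 CPM in Schwann cell-like cells and Map2k3 at 157 CPM in macrophage-like cells. Of 10 feedback inhibitors, 1 was placed, Dusp5 in T cell-like cells at 420 CPM, with Dusp2 (434 CPM in lymphatic endothelial cell-like cells) and Spred1 (264 CPM in macrophage-like cells) unplaced. None of 20 TGF-beta genes was placed, and Ccn2 was highest in smooth muscle-like cells at 1577 CPM and Ltbp4 in endothelial cell-like cells at 1025 CPM (in 4 of 6 libraries).

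None of 18 genes of the immediate early and dissociation response list, called immediate early genes here, was placed. The transcription factors Fos and Jun were highest in Schwann cell-like cells at 7363 and 4106 CPM (in 6 and 5 of 6 libraries). The interferon list (0 of 8; Bst2 531 and Isg15 263 CPM at most) and the unfolded protein list (0 of 10; Hspa5 1969 and Calr 1185 CPM in fibroblast-like cells) likewise had no placed gene. Of 17 regional identity genes, 1 was placed, Hoxc10 in pericyte-like cells at 71.0 CPM, and Hoxa7 and Hoxa5 reached at most 94.9 and 92.0 CPM. Of 11 bestrophins and other chloride channels, 0 were placed. Clca1 reached 6773 CPM in epithelial cell-like cells, of which library 5 held 297 of 348, but was highest there in only 1 of 3 libraries with values from 0 to 7480 CPM, and Clic4 876 CPM in smooth muscle-like cells against 799 CPM in pericyte-like cells. Among bestrophins, Best1 was highest in fibroblast-like cells at 7.85 CPM.

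Within the smooth muscle-like class, 4 clusters were compared. Cluster 0 held 11267 cells, cluster 10 held 1315, cluster 18 held 432 and cluster 23 held 250. In cluster 10, 32 of 143 list genes at 50 CPM or more were higher and 18 lower. By list, 9 of 18 immediate early genes and 4 of 7 matrix proteases were higher, and 5 of 9 elastic fibre genes and 6 of 14 collagens were lower, with 1 collagen higher. Of 22 contractile regulators and ion handling genes, 4 were higher and 2 lower. These counts were not tested for enrichment. For the immediate early genes, a response to dissociation cannot be told apart from a program of the cluster. Adamts4, a proteoglycan-cleaving protease, stood at 110 CPM against 1.73 CPM in the rest of the class, 64.0 times as high. Phospholamban (Pln) stood at 350 against 7.71 CPM, the matricellular gene Thbs1 at 802 against 25.4 CPM and Ednra at 66.7 against 5.49 CPM. Notch3 (465 against 44.4 CPM), desmin (Des, 1393 against 156 CPM) and P2rx1 (264 against 60.2 CPM) were also higher, as were the immediate early genes Atf3, Junb, Fosb, Egr1 and Nr4a1. Lower genes included Mfap4, which stood at 44.9 against 405 CPM, Fbln5 at 117 against 444 CPM, Fbn1 at 48.1 against 158 CPM and Eln at 778 against 1692 CPM. Itga8 (514 against 1627 CPM) and Col3a1 (315 against 827 CPM) were lower too.

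In cluster 23, 23 of 146 genes were higher and 12 lower. By list, 4 of 11 elastic fibre genes, 5 of 18 TGF-beta genes and 5 of 10 modulated smooth muscle genes were higher, with 2 of the latter lower, and 3 of 20 contractile regulators and ion handling genes were lower. Thrombomodulin (Thbd) stood at 197 against 16.8 CPM, Ltbp2 at 348 against 34.5 CPM, Vcam1 at 148 against 21.7 CPM and Fbln1 at 122 against 19.8 CPM. The chondrogenic regulator Sox9 (90.0 against 16.9 CPM), aggrecan (Acan, 97.2 against 16.8 CPM) and Fbln5 (1689 against 387 CPM) were also higher. Desmin (18.9 against 276 CPM), P2rx1 (6.53 against 80.7 CPM), Hoxa7 (6.18 against 64.1 CPM) and Hoxa5 (25.1 against 55.7 CPM) were lower. Cluster 23, of 250 cells, was not found again with at most 10% mitochondrial counts or with doublets kept.

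The rest of the class in these ratios is mostly cluster 10 when cluster 0 is considered, so the 4 genes higher and 27 lower in cluster 0 largely mirror cluster 10. Postn stood at 706 against 182 CPM, Mfap4 at 404 against 132 CPM, Cbr2 at 245 against 97.2 CPM and Col3a1 at 830 against 408 CPM. Cluster 18 had a median of 1866 UMIs per cell against 9410 or more in the other clusters. It had 0 genes higher and 18 lower, among them the immediate early genes Fos, Jun, Junb and Egr1, and its largest ratios were Apoe (1.44), Bst2 (1.41), Cbr2 (1.22) and Ppp1r14a (1.14), none of which met the rule. Its share of shallow cells limits any reading of it.

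**Figure D3:**
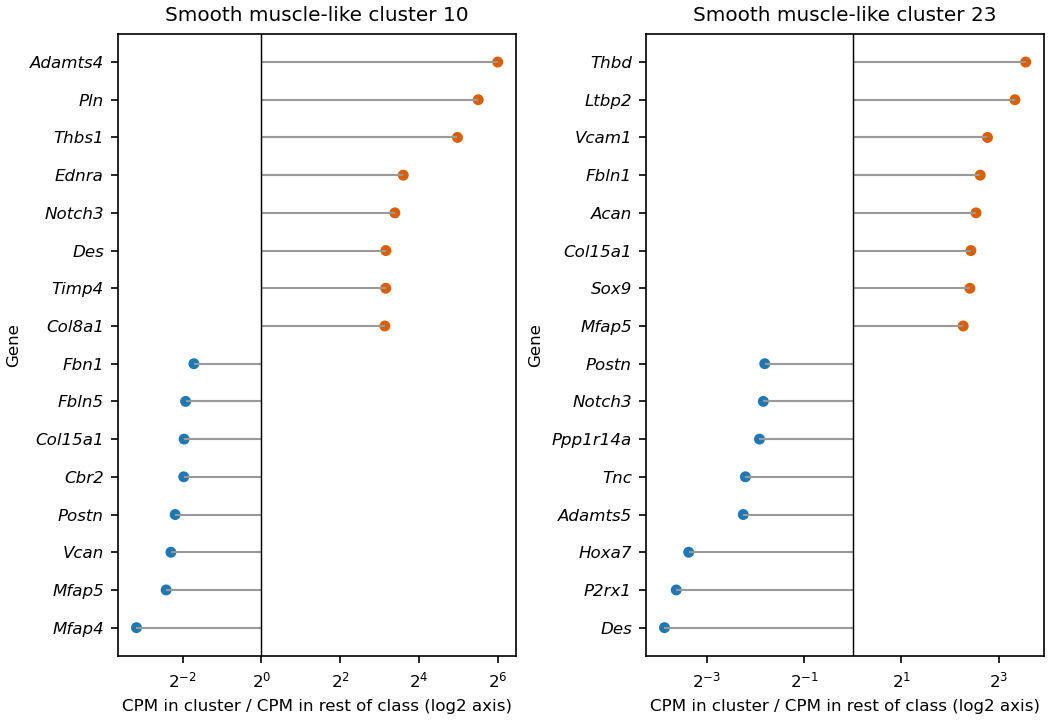
Ratio of CPM in smooth muscle-like clusters 10 and 23 to CPM in the rest of the class (log2 axis), for the 8 list genes with the largest and the 8 with the smallest ratio among those passing the size rule. Adamts4 stands at 64.0 times in cluster 10 and Thbd at 11.8 times in cluster 23, while Mfap4 and Des lie lowest.

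Between libraries, list genes in smooth muscle-like cells varied, on the median, by more than the ratio of 1.04 that counting error gave for unchanged genes in the simulation. The simulated genes were more abundant than many list genes, such as Ccl6 at a median of 6.58 CPM, for which counting error is larger. Counting error also leaves out differences between animals and preparations, so 1.04 is not a reference for them. Of 227 genes with at least 50 counts in each library, 56 differed at least 2-fold between the highest and lowest library, and the median ratio was 1.52. Ccl6 varied most, 10.6 times (counting interval 7.88 to 14.3), between 1.76 CPM in library 6 and 18.6 CPM in library 4, or 5.63 times without library 6 and 6.17 times without library 4. The cardiac transcription factor Tbx20 varied 9.13 times with its highest value, 23.1 CPM, in library 2. Hand2 also peaked in library 2 (32.5 CPM) and varied 6.09 times, falling to 3.30 times without that library. Tbx20 fell to 2.87 times without library 2 and to 5.89 times without library 3. Library 2 also held 211 of the 355 cells of fibroblast-like cluster 20, in which Tbx20 stood at 1074 CPM, and 38 of the 49 mesothelial cell-like cells. Adamts4 varied 6.62 times, between 2.90 CPM in library 3 and 19.2 CPM in library 1, or 3.28 times without library 3. Ccl7 varied 6.33 times, between 2.41 CPM in library 6 and 15.3 CPM in library 5, or 2.59 times without library 6 and 4.12 times without library 5. Pln varied 5.86 times, between 16.6 CPM in library 3 and 97.1 CPM in library 4. The steadiest genes were Efemp2, between 96.7 and 106 CPM, and Timp2, between 439 and 473 CPM.

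By list, the widest median ratios were those of cytokines and chemokines (2.81, 8 of 11 genes at least 2-fold) and of endothelial flow and activation (2.22, 4 of 6). The MEKK2/3 and MAP kinase cascade had a median of 1.26 with 0 of 15, and the listed aneurysm genes 1.34 with 0 of 17. The share of cluster 10 among smooth muscle-like cells lay between 3.53% in library 3 and 25.7% in library 4. Smooth muscle-like cells of library 5 had a median of 6153 UMIs, against 11296.5 to 12459 in the other libraries. When every cell was thinned to 2000 UMIs, 28 of 164 genes differed at least 2-fold.

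Sex-linked transcripts divided the libraries. In smooth muscle-like cells Xist, the RNA of the silenced X chromosome, stood at 171, 160 and 261 CPM in libraries 1, 3 and 4 and at 0.303, 0.184 and 0.379 CPM in libraries 2, 5 and 6. The Y-linked gene Ddx3y lay between 86.7 and 131 CPM in the 6 libraries. In libraries 1, 3 and 4, cells with Xist alone numbered 480, 376 and 372 and cells with Y-linked UMIs alone 1237, 1150 and 673. Only 93, 118 and 97 cells held both. The labels give neither the sex nor the number of animals behind a sample.

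**Figure D4:**
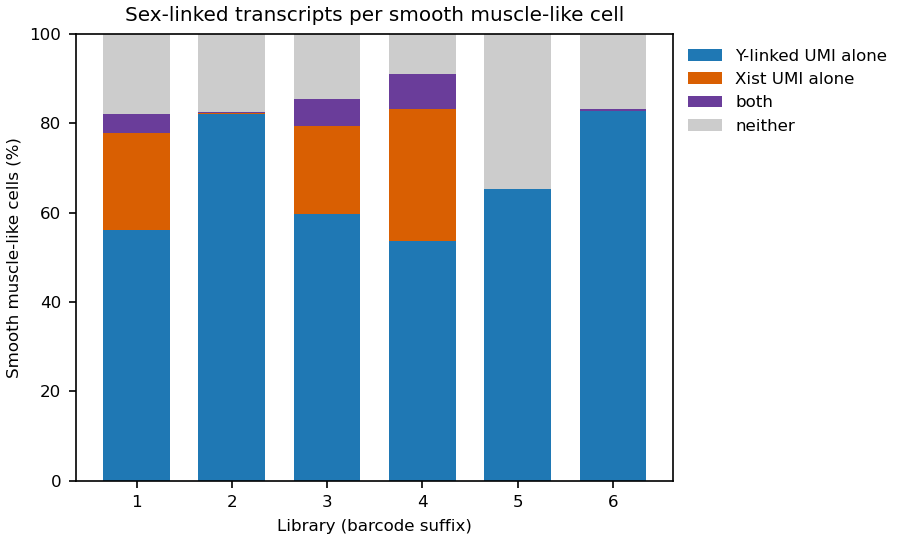
Share of smooth muscle-like cells (%) in each library with UMIs of Y-linked genes alone, of Xist alone, of both or of neither. Cells with Xist alone appear in libraries 1, 3 and 4 (480, 376 and 372 cells) and number at most 2 in libraries 2, 5 and 6.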

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

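Of 32 quantities compared between the 6 libraries, 9 had 1 library further from the others than Dixon's 95% limit allows. Chance would give about 5% for independent, normally spread quantities chosen beforehand. These include shares that depend on each other, Best3 with few UMIs and Tbx20, named for its wide library ratio, so the 5% is only a rough guide. The test on lung genes was written before its values were read, and the levels in cluster 12 were examined after the result was seen.

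Library 5 had higher shares of T cell-like, B cell-like and epithelial cell-like cells than the other libraries. T cell-like cells made up 4.17% of it (next highest library 1.40%), B cell-like cells 3.11% (next 0.253%) and epithelial cell-like cells 2.14% (next 0.308%). Its epithelial cell-like cells expressed the airway genes Scgb1a1 at 46061 CPM and Bpifa1 at 47221 CPM and the surfactant gene Sftpc at 1780 CPM. Fibroblast-like cluster 12, with 932 of its 1048 cells in library 5, carried Cxcl10 (1111 against 34.2 CPM in other fibroblast-like cells of library 5), Ifit3 (833 against 25.8 CPM) and Sftpc (686 against 6.20 CPM). Scgb1a1 stood in that cluster at 179 CPM against 157 CPM.

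Smooth muscle-like cells made up 27.1% of library 5, so their share was not low there. Against the median of the other libraries, the share of epithelial cell-like cells stood at 44.2 times, of B cell-like cells at 16.8 times and of T cell-like cells at 4.16 times. Endothelial cell-like (0.538 times), pericyte-like (0.632), lymphatic endothelial cell-like (0.751) and macrophage-like cells (0.892), which lung tissue would also bring, were not raised. By contrast, the unnamed cluster led by Lyz1, Ear2 and Chil3 had 524 of its 959 cells in library 5. Lung tissue carried along at dissection is a candidate source. In its test 14 of 26 lung genes (53.8%) were highest in library 5 and at least 5 times the median of the others. This fell short of the share above 75% set in advance, so the test left the source open. All 6 type II alveolar, 4 of 6 airway and 3 of 5 alveolar macrophage genes met that rule, but only 1 of 4 type I alveolar and 0 of 5 lung fibroblast genes did. Of the 18 genes with a median under 1 CPM in the other libraries 13 met it, against 1 of the 8 others. Inmt and Limch1 stood at 171 and 150 CPM or more in every other library, where a 5-fold rise is hard to reach. Sftpa1, Sftpd and Scgb3a2 had 0 CPM in the other libraries and 45.6, 21.6 and 303 CPM in library 5. In cluster 12 itself, against other fibroblast-like cells, Tcf21 (98.6 against 20.6 CPM), Limch1 (106 against 31.7 CPM), Fgfr4 (1.65 against 0.124 CPM) and Inmt (874 against 714 CPM) were higher and Wnt2 (4.96 against 19.7 CPM) was lower. No biological explanation was tested, since no library has a known genotype.

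Library 5 also held the most barcodes, 16269 against 10524 in the next library. Scrublet called 11.5% of its barcodes doublets, against 4.99% in the next library. Its automatic threshold was 0.116 in library 5 and 0.174 to 0.202 in the others, while the median score of 0.0340 lay within theirs (0.0273 to 0.0422). The higher call rate may thus follow the threshold. Its smooth muscle-like cells had a median of 6153 UMIs, against 11296.5 in the next lowest library. In library 1, Best3 stood at 0.446 CPM in smooth muscle-like cells from 11 UMIs, against 0.123 CPM in the next library. In library 2, mesothelial cell-like cells made up 0.540% against 0.0722% in the next library. Also in library 2, Tbx20 stood at 23.1 CPM in smooth muscle-like cells against 7.27 CPM in the next library, and 211 of the 355 cells of fibroblast-like cluster 20, with Tbx20 at 1074 CPM, were in library 2.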

How the results depend on the processing

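Of 391 recomputed values, 343 stayed within the range set for them and 48 moved. Reversals of direction were not scored. For class shares the range was the standard deviation between libraries, which is wide where 1 library stands out. The median T cell-like share fell from 1.01% to as low as 0.352% and still counted as unmoved. The largest smooth muscle-like cluster on its own and a minimum of 2 sex-linked UMIs were alternatives chosen after the data were seen. The counts of list genes higher and lower in cluster 10 stayed within 1.5 times of 32 and 18 under each alternative that gave a value. Among these, the alternatives that left out 1 library kept the clusters fixed. Where values moved, the cause was not tested unless it is named.

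With at least 200 genes per cell, 2 genes were placed in smooth muscle-like cells instead of 7. With at most 10% mitochondrial counts, 16 were placed there and 11 in macrophage-like cells (22 before), and 17 genes were higher in cluster 0 (4 before). With doublets kept, the median share of macrophage-like cells was 7.33% instead of 5.95%, and 4 genes were placed in fibroblast-like and 11 in smooth muscle-like cells. In that setting 18 genes were higher in cluster 0 and 1 higher in cluster 18. At Leiden resolution 1.0 the median share of fibroblast-like cells was 26.6% instead of 32.3%, and 16 genes were placed in any class, 0 in fibroblast-like, 0 in smooth muscle-like and 11 in macrophage-like cells. Placement in smooth muscle-like and fibroblast-like cells therefore depends on how the cells are divided. Like counts did not mean like genes: of the 50 genes placed in a class, 38 were placed in the same class with the lower gene limit (46 placed), 32 with the stricter mitochondrial limit (48 placed), 28 with doublets kept (38 placed, 2 of the 50 in another class) and 15 at resolution 1.0 (16 placed). Leaving out 1 library, with the clusters and names of all 6 kept, retained between 46 and 50 of them, so this does not test the clustering. Pericyte-like cells were not separate in these 4 settings that changed the cells or the resolution.

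By construction, a size rule of 2 times placed more genes: 94 in any class, 20 in fibroblast-like, 16 in smooth muscle-like and 10 in endothelial cell-like cells. A rule of 8 times placed 27 in any class, 3 in fibroblast-like, 2 in endothelial cell-like and 0 in smooth muscle-like cells. For smooth muscle-like cells, the smooth muscle marker RNA found in the other classes may limit this count. Leaving out 1 library at a time, Best3 in smooth muscle-like cells ranged from 0.0777 CPM (without library 1) to 0.168 CPM (without library 5), and the genes higher in cluster 18 from 0 to 1 (without library 6). After thinning to 2000 UMIs, 28 genes differed at least 2-fold between libraries, of 164 that could still be tested, and 21 of them were among the 56 found at full depth. Cluster 18 had no counterpart with the lower gene limit or the stricter mitochondrial limit, and cluster 23 had none with the stricter mitochondrial limit or with doublets kept (best share of cells over union 0.0225 and 0.0212), so those settings give no value for them. Best3, at 26 UMIs in all, is limited by depth in every setting.

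No paired analysis was possible because no cell can be tied to a sample, and the replicate numbers of the labels were therefore not used. For the same reason other settings of the genotype comparison (edgeR with a block, DESeq2, no filter on low counts, leaving out samples, and other cell and doublet limits in that comparison) were not run.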

Other observations

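Endothelial cell-like clusters differed in the list genes they carried. In cluster 4 (2726 cells) 24 list genes were higher and 35 lower, with Lpl at 2194 against 60.4 CPM in the other endothelial cell-like cells, Gpihbp1 at 3231 against 140 CPM and Cd36 at 4660 against 640 CPM. In cluster 5 (2265 cells) 24 were higher and 31 lower, with Gja5 at 404 against 36.7 CPM, Thbs1 at 621 against 59.7 CPM and Eln at 1514 against 331 CPM. In cluster 6 (2255 cells) 15 were higher and 26 lower, and the higher genes included Ackr1 (177 against 0.994 CPM), Sele (86.4 against 3.38 CPM) and Selp (839 against 89.9 CPM). Cluster 11 (1122 cells) held Hey1 (132 against 24.7 CPM) and Notch3 (50.3 against 9.81 CPM). The tests on sex-linked co-occurrence, on X-linked escape genes and on the share of cluster 10 were chosen after the result was seen, and these clusters of other classes were examined after the data were seen.

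Fibroblast-like clusters also differed in the list genes they carried. Cluster 1 (7414 cells) was rich in Ccn2 (1298 against 274 CPM in other fibroblast-like cells) and Mfap4 (1571 against 348 CPM), and cluster 8 (1669 cells) in Fn1 (5206 against 406 CPM) and Fbn1 (1305 against 247 CPM). Cluster 2 (6124 cells) held Cxcl14 (82.7 against 18.1 CPM) and Lpl (494 against 189 CPM). Cluster 20 (355 cells, 211 of them in library 2) held the cardiac transcription factor Tbx20 at 1074 against 7.42 CPM and Sox9 at 420 against 62.0 CPM, with Hoxa7 low at 7.30 against 50.1 CPM. Cluster 12 (1048 cells) held Rsad2 (298 against 4.69 CPM) and Cxcl10 (953 against 17.1 CPM).

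Several Hox genes of the trunk were low in cluster 23 of the smooth muscle-like cells. Hoxa7 had been seen to be low, and cells of a more proximal aortic segment are a candidate source. The test written before their values were read used Hoxb7, Hoxc6, Hoxc8, Hoxc9 and Hoxc10. All 5 were lower in cluster 23 beyond the counting interval, for example Hoxc10 at 1.03 against 16.7 CPM and Hoxb7 at 3.09 against 18.8 CPM. Hoxa3 (35.7 against 26.5 CPM) and Hoxa4 (13.1 against 6.93 CPM) were higher, Hoxb4 (24.4 against 37.1 CPM) was lower and Hoxa2 (6.18 against 4.59 CPM) lay within counting error, so the anterior genes went both ways. A segment origin remains a hypothesis because the dissected region is not given.

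Libraries 1, 3 and 4 held cells with Xist and cells with Y-linked transcripts. Free RNA or doublets would put both into the same cells, but smooth muscle-like cells with both were at most 0.362 times as many as independence gives, which argues against them as the whole source. Cells of female and male animals in 1 library may explain it. The X-linked escape genes Kdm6a, Kdm5c and Eif2s3x were higher in Xist cells in each library, in smooth muscle-like and fibroblast-like cells, with a lowest ratio of 1.12. Whether animals were pooled in a sample or cells were exchanged between libraries stays open.

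Between these cells of the same library, fibroblast-like cells differed in 6 autosomal genes higher and 16 lower in cells with Xist, where random splits gave at most 2. Sult1e1, an oestrogen sulfotransferase, stood at 4.90, 1.20 and 0.897 CPM in Xist cells of libraries 1, 3 and 4 against 58.3, 94.3 and 73.2 CPM in Y-linked cells. C7 (74.9, 113 and 65.9 against 312, 396 and 360 CPM), Penk, Gpx3 and Dpep1 were also lower, and Acp5 (63.2, 70.7 and 57.7 against 29.1, 36.8 and 28.6 CPM) was higher. Sult1e1, C7 and Penk are also leading genes of fibroblast-like cluster 2, so their levels in the class also depend on its mix of clusters. Within cluster 2, C7 stood at 136, 136 and 125 against 618, 677 and 629 CPM. Of the 22 genes, which were chosen in the same cells, 6, 17 and 11 still met the ratio in all 3 libraries within clusters 1, 2 and 8. Endothelial cell-like cells had 2 higher and 5 lower, where random splits gave at most 2.

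Smooth muscle-like cells had 2 higher (Ghr, Pcsk5) and 2 lower (Trnp1, Hbb-bs), where random splits gave at most 3. Ghr stood at 51.9, 157 and 72.5 CPM in Xist cells against 31.6, 44.1 and 33.8 CPM, and Trnp1 at 28.5, 39.4 and 37.5 against 62.9, 68.7 and 64.9 CPM. The Hbb-bs difference rests on few cells, since the 10 highest Y-linked cells held at least 93.2% of the haemoglobin UMIs of the Y-linked cells in each library. Macrophage-like cells had 7 higher and 3 lower, no more than the 10 that random splits reached. With at least 2 UMIs the totals were 25 in fibroblast-like, 5 in smooth muscle-like, 4 in endothelial cell-like and 12 in macrophage-like cells (22, 4, 7 and 10 before), where random splits reached 2, 1, 4 and 28, so the endothelial cell-like count no longer stood above them. The number of animals is unknown, so this compares cells and not animals and was not tested.

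In smooth muscle-like cells, part of the spread between libraries lay in cluster 10 genes and in genes of other classes. Abundant genes highest in smooth muscle-like cells varied too. Rgs5 ranged from 1129 CPM in library 1 to 4091 CPM in library 6 and Hspa1b from 241 to 921 CPM in the same libraries, and the source of this spread was not tested. In cluster 0 alone, the ratios of Adamts4, Pln, Thbs1, Ednra, Notch3 and Des fell to a median of 0.474 of their value in the class (Pln from 5.86 to 3.07 times), so the share of cluster 10 may account for part of their spread. For genes whose smooth muscle-like level was under 5% of their highest class, such as Ccl6, free RNA of those classes is a candidate source. Over these 32 genes the library levels followed those of the other cells with a median rho of 0.286, below the limit of 0.4 set in advance, which is also the median of genes highest in smooth muscle-like cells, so this could not be decided. A narrower set looked at afterwards, the 25 of them at least 2-fold apart, gave 0.543. The 8 equally spread genes highest in smooth muscle-like cells gave 0.743. They are no clean reference, because free RNA of smooth muscle-like cells in the other cells could also raise their value. In library 5, smooth muscle-like cells held the airway genes Scgb1a1 at 139 CPM and Bpifa1 at 86.2 CPM. Transcripts most abundant in epithelial cell-like cells thus occurred among them there, but this does not decide the case of the 32 genes.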
